A study of Mus musculus with 22 samples.

How the data were processed

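Ribosome-bound RNA was measured in the anterior cingulate cortex of male C57BL6/J mice. Per the labels, a retrograde adeno-associated virus injected in the habenula carried mCherry fused to the ribosomal protein RPL10a under a CaMKIIa promoter, so that ribosomes of cortical glutamatergic neurons projecting to the lateral habenula carried the tag. Immunoprecipitation of the tag gave the IP fraction, and the RNA of the tissue before purification gave the input fraction. The 22 libraries fell into 4 groups: IP (n = 3) and input (n = 3) of naive mice, and IP from mice with a sham operation (n = 8) or a cuff (n = 8). The series title names chronic pain and depression. The naive libraries and the sham and cuff libraries came from 2 library projects with a separate table each, so every test was run within a table, and levels named across the tables carry no test.

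Per the labels' protocols, 1 ng of total RNA was turned into full-length cDNA with a SMART-Seq v4 kit and 12 PCR cycles, and 600 pg of cDNA were tagmented with Nextera XT, followed by 12 cycles of library amplification. Such libraries carry no molecular identifiers and do not mark strand, so duplicate reads were counted and reads of a gene and its antisense partner could not be told apart. The authors deposited whole-number read counts per gene, not normalized, per the file headers. Per the submitters' processing notes, the tools were bcl2fastq 2.20.0.422, STAR 2.5.3a, HTSeq 0.6.1p1 and DESeq2 1.16.1 with the mm10 build. The annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. The tables held 29493 genes for the naive libraries and 32051 for the sham and cuff libraries, with gene symbols as deposited, and 99.78% of the identifiers in each were found in GENCODE M21 (GRCm38, the same assembly as mm10). Coordinates and transcript lengths were taken from that release.

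Total counts ran from 34.7 to 54.1 M reads in the naive libraries and from 24.97 to 42.2 M reads in the sham and cuff libraries. No 2 libraries held identical values, and the closest pair differed by 24.0 times the sampling noise (chi-square per degree of freedom over genes with a mean count of 50 or more), so each library counted as 1 replicate. The labels do not state that each library came from a separate animal, so p-values measure the spread between these libraries.

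The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Genes passing edgeR's filterByExpr (minimum count 10) were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, robust quasi-likelihood fit, F test, Benjamini-Hochberg adjusted p below 0.05. Fold changes are IP over input and cuff over sham. Standard errors (SE) are the absolute log2 fold change over the square root of F. CPM are read counts scaled to a common total by the TMM-scaled library size. The 35 gene lists cover cell types, cortical layers, receptors and channels, synaptic parts, ribosomal and mitochondrial genes, activity, stress and hormone responses. They were tested with camera on voom values (limma 3.58.1) with a preset inter-gene correlation of 0.01, and again with an estimated correlation, adjusted over the lists. For cuff against sham, the 500 genes with the smallest p called lower and the 500 called higher in IP than input made 2 further lists. A list mean is the mean of log2(CPM + 1) over its tested members. The non-neuronal index is that mean over 69 members of the astrocyte, oligodendrocyte, microglia and vascular lists. Differences in list means and in the index were tested with exact two-sided permutation tests. With 3 against 3 libraries an exact permutation test cannot go below p = 0.1, and with 8 against 8 the smallest exact p is 0.000155.

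Named genes were taken by rule. For IP against input these were Rpl10a, then among called genes with an average log2 CPM of 3 or more, no overlap between the fractions and a symbol that is not Gm with digits, a Rik clone or mitochondrial, the 12 with the largest and the 12 with the smallest log2 fold change. For cuff against sham the rule took called genes, and where fewer than 5 passed, the 10 with the smallest p per direction (average log2 CPM of 1 or more), given as not passing. Up to 4 members of each list were added by smallest p. Some genes that the rule names are not reported here. Of the 26 genes named by rule or as checks for IP against input, 15 overlap another annotated gene, 13 of them a gene on the opposite strand. Among the 22 for cuff against sham, 12 overlap another gene and 7 a gene on the opposite strand. Values of these genes may hold reads of the neighbour.

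Alternatives were DESeq2 1.42.0, limma voom with and without sample weights, other normalizations and count filters, a fit without robust estimation, other thresholds, 1 surrogate variable (sva 3.50.0), the non-neuronal index as a covariate, the replicate number as a block, and each library left out. The replicate numbers of the naive libraries come from the labels. Deviations from the group means of the IP and input libraries with the same number correlated at 0.31, 0.23 and 0.15 (median of other pairs −0.14). These numbers may thus pair the fractions, but with 3 libraries per fraction such a match can arise by chance. The main IP and input tests took the libraries as unpaired. With the number as a block, 2904 genes were higher and 2980 lower in IP. Sham and cuff numbers did not pair (2 of 16 libraries were closest to the one with their number). In data simulated from the real means and library sizes with 200 changed genes, the same steps recovered 23.9% of genes changed 1.5-fold, 71.6% at 2-fold and 65.2% at 3-fold for IP against input (16441 genes), with 11 false calls. For cuff against sham (15609 genes) they recovered 41.8%, 70.1% and 84.8% at those folds, with 3 false calls. The simulated genes were drawn independently, so these percentages need not hold where genes vary together.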

Results

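RNA bound to tagged ribosomes of anterior cingulate neurons that project to the lateral habenula was sequenced and counted per gene. Naive mice gave 3 IP and 3 input libraries, with mean total counts of 42.2 ± 6.78 M reads (SD, n = 3) and 47.9 ± 5.55 M reads (SD, n = 3). Sham mice gave 8 IP libraries with 32.0 ± 4.41 M reads (SD, n = 8), and mice with a cuff gave 8 with 35.7 ± 3.09 M reads (SD, n = 8). The cuff group is the chronic pain group of the series title, which links such pain to depression. Ddx3y, a Y-linked gene, lay between 29.5 and 65.2 CPM in the 22 libraries, as the labels' male mice would have. Xist, the transcript of the inactive X chromosome, had 3 reads in the 16 sham and cuff libraries together. It was not among the genes listed for the naive libraries, so it gives no check there.

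The first comparison asked which transcripts the purification enriched. In naive mice the IP fraction held more RNA of layer 5 extratelencephalic neurons, the deep-layer cells that project out of the cortex to subcortical targets, and less RNA of inhibitory neurons, astrocytes, oligodendrocytes, their precursors and microglia. Transcripts of ribosomal proteins and of the nuclear-encoded respiratory chain were higher in IP, and transcripts encoded in mitochondria were lower. These 15 of 35 list calls rest on camera's preset correlation, and with an estimated correlation 0 of the 35 lists passed after adjustment. With the preset correlation, the 9 other splits of these libraries, which mix IP and input, called a median of 10 lists (highest 16). The number of list calls thus does not set the real grouping apart, whereas these splits called 0 genes. Of 16878 genes tested, 2527 were higher and 2412 lower in IP than input (edgeR, adjusted p below 0.05), 612 and 778 of them by at least 2-fold. Without input replicate 3 the counts were 1093 and 1265, without input replicate 2 they were 1357 and 1429, and without IP replicate 1 1646 genes were higher.

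Rpl10a, the host gene of the tag, was 5.74 ± 0.61 CPM in IP and 3.26 ± 0.80 CPM in input (SD, n = 3 each), a log2 fold change of 0.82 ± 0.26 (SE, edgeR adjusted p = 0.0409). The call ended under upper-quartile or library-size scaling and without any library other than input replicate 1, with an adjusted p of up to 0.171. The largest rise among the named genes was that of Rpl10a-ps1 (ENSMUSG00000084416, mm10 chromosome 1, 64993951 to 64994604), a processed pseudogene. It rose from 1.87 ± 1.66 to 27.0 ± 5.57 CPM, a log2 fold change of 3.84 ± 0.51 (edgeR adjusted p = 0.00145). All 605 of its 50-base windows occur in the coding transcripts of Rpl10a (chromosome 17, 28328471 to 28331033), so the reads of these genes are uncertain between them.

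Layer 5 extratelencephalic markers rose as a group, with 9 of 13 tested members higher and 0 lower (11 higher when adjusted over the list alone), a median log2 fold change of 1.00 (camera adjusted p = 1.06e-07, adjusted p = 0.318 with an estimated correlation). Crym, a thyroid hormone binding protein, rose from 247 ± 4.85 to 712 ± 99.4 CPM (log2 fold change 1.53 ± 0.11). The transcription factors Pou3f1 (chromosome 4, 124656807 to 124660655) and Fezf2 rose by log2 fold changes of 1.90 ± 0.16 and 1.55 ± 0.14, and the natriuretic peptide receptor Npr3 by 1.59 ± 0.19. Upper layer markers fell, with 8 of 13 lower and 1 higher (9 and 1 adjusted over the list alone, camera adjusted p = 0.00351, adjusted p = 0.289 with an estimated correlation). The homeobox factor Cux1 fell by 0.81 ± 0.10 on the log2 scale and Wfs1 by 1.14 ± 0.15, whereas Lamp5 was higher by 0.82 ± 0.11. Layer 6 and 6b markers had 3 of 14 members lower, among them Cplx3 at a log2 fold change of −1.35 ± 0.23 and Tle4 at −0.68 ± 0.14 (3 adjusted over the list alone). That list did not pass (camera adjusted p = 0.0762) and passed with the replicate number as a block (adjusted p = 0.032), without input replicate 1 (0.0218) or without IP replicate 3 (0.0414). Members of the layer 5 intratelencephalic list went both ways (2 higher, 3 lower, of 8, camera adjusted p = 0.58), with Etv1 at 0.95 ± 0.10 and Pamr1 at −1.24 ± 0.20. In the near-projecting list 1 of 6 was higher and 2 lower (adjusted p = 0.285).

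General glutamatergic markers did not shift as a list, with 4 of 15 higher and 5 lower and a median of 0.03 (camera adjusted p = 0.686). Nrgn, a postsynaptic calmodulin-binding protein, rose by 1.41 ± 0.22 on the log2 scale and Nptx1 fell by 1.22 ± 0.20. The level of Slc17a7, the vesicular glutamate transporter of cortical neurons, was 997 ± 80.6 CPM in IP and 977 ± 142 CPM in input (SD, n = 3 each). Slc17a7 here, and S100b among the astrocyte markers, were chosen after their values were seen.

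**Figure D1:**
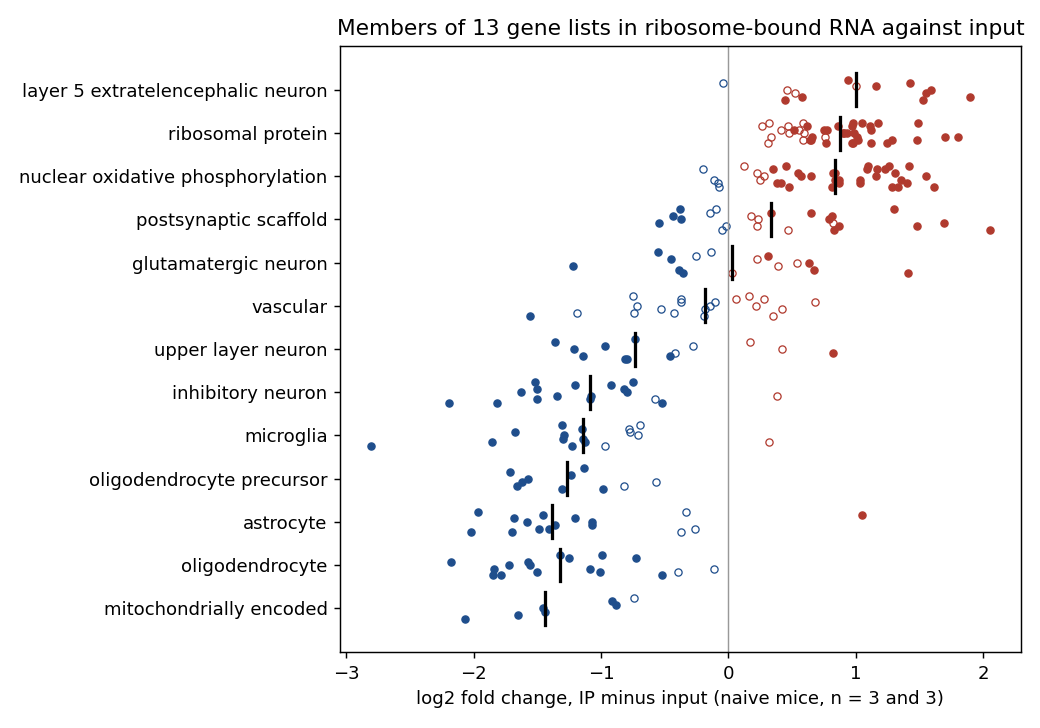
Log2 fold change of each tested member of 13 gene lists, IP over input in naive mice (x axis; n = 3 and 3 libraries). Points are genes, filled where edgeR's adjusted p was below 0.05, red above and blue below 0, and the black bar is the list median. The 13 layer 5 extratelencephalic markers have a median of 1.00, and the 17 oligodendrocyte markers a median of −1.32.

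Markers of other cell types fell in IP. Inhibitory neuron markers had 15 of 17 lower (16 adjusted over the list alone, camera adjusted p = 1.49e-08, adjusted p = 0.289 with an estimated correlation). Gad1, which makes GABA, fell from 404 ± 22.3 to 142 ± 23.1 CPM. Oligodendrocyte markers had 15 of 17 lower (15 adjusted over the list alone, camera adjusted p = 1.56e-09, adjusted p = 0.385 with an estimated correlation), with the myelin gene Mag at −2.18 ± 0.30. Their precursors had 8 of 10 lower (10 adjusted over the list alone, camera adjusted p = 3.17e-06, adjusted p = 0.228 with an estimated correlation), with Sox10 at −1.66 ± 0.20. Astrocyte markers had 12 of 16 lower and 1, S100b at 1.05 ± 0.22, higher (12 and 1 adjusted over the list alone, camera adjusted p = 2.19e-09, adjusted p = 0.289 with an estimated correlation). Acsbg1 fell from 238 ± 22.1 to 58.8 ± 1.04 CPM and Sox9 had a log2 fold change of −1.49 ± 0.13. Microglia markers had 10 of 16 lower (11 adjusted over the list alone, camera adjusted p = 6.96e-06, adjusted p = 0.289 with an estimated correlation). Csf1r, the receptor microglia need to survive, fell 6.99-fold, from 32.0 ± 3.24 to 4.54 ± 1.87 CPM.

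Of 20 vascular markers tested, 1 was lower, the pericyte gene Pdgfrb at −1.56 ± 0.29 (1 adjusted over the list alone), and the list median was −0.19 (camera adjusted p = 0.675). With the replicate number as a block, Slc2a1 (−0.53, edgeR adjusted p = 0.0397) and Slco1a4 (−0.69, edgeR adjusted p = 0.0314) were called lower too. The vascular list did not pass with that block (camera adjusted p = 0.408). The difference between this list and those of the other cell types was not tested. Their list mean differed by −0.11 ± 0.28 (SE) between the fractions (exact permutation p = 0.8; the smallest possible is 0.1). Meningeal and fibroblast markers had 2 of 9 lower, Col1a2 and Slc6a13 (2 adjusted over the list alone, camera adjusted p = 0.0268, adjusted p = 0.555 with an estimated correlation). Striatal markers had 2 of 10 lower, Drd1 and Pde10a (3 adjusted over the list alone, camera adjusted p = 0.0326, adjusted p = 0.571 with an estimated correlation). The meningeal call ended without input replicate 2 (adjusted p = 0.0537), input replicate 3 (0.0641) or IP replicate 2 (0.0646), and the striatal call without input replicate 1 (0.188) or IP replicate 2 (0.0808). Among the genes, the calls of Col1a2 (adjusted p up to 0.112, without input 2 or 3 or IP 2 or 3), Slc6a13 (up to 0.13, without any library but input 1) and Pde10a (up to 0.11, without any library but IP 1) ended when 1 library was left out. Blood (1 lower of 5, adjusted p = 0.107), choroid plexus and ependyma (1 lower of 6, adjusted p = 0.206) and habenula markers (1 lower of 5, adjusted p = 0.221) did not pass. Blood markers passed without IP replicate 1 (0.0182). Outside the lists, the genes that fell most included Fam163a, Arhgef10, Myorg, Vcam1, Btbd11, Tmem63a and Cpt1a, with log2 fold changes between −2.40 (Fam163a) and −2.05 (Cpt1a). The kinase Pdk4, which restrains glucose oxidation, fell by 2.35 ± 0.32.

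Transcripts of the postsynaptic density scaffold rose, with 10 of 23 higher and 4 lower (10 and 4 adjusted over the list alone, camera adjusted p = 0.00694, adjusted p = 0.555 with an estimated correlation). The 3 Shank genes, which encode master scaffolds of excitatory synapses, led the list: Shank1 (chromosome 7, 44310253 to 44360572), Shank2 and Shank3 had log2 fold changes of 2.05 ± 0.17, 1.48 ± 0.12 and 1.69 ± 0.18. Voltage-gated sodium and calcium channels rose (6 of 23 higher, 2 lower; 8 and 3 adjusted over the list alone, camera adjusted p = 0.0268, adjusted p = 0.289 with an estimated correlation), among them the T-type channel Cacna1h at 1.32 ± 0.16. That call ended without input replicate 1 (adjusted p = 0.0511). Monoamine and neuromodulator receptors fell (10 of 37 lower, 2 higher; 10 and 2 adjusted over the list alone, camera adjusted p = 0.0317, adjusted p = 0.555 with an estimated correlation), with Oprd1 at −1.74 ± 0.27, Drd1 at −1.14 ± 0.20 and Ntrk2 at −0.76 ± 0.11. That call ended without input replicate 2 (adjusted p = 0.0702) or IP replicate 3 (0.0583). Lists that went both ways and did not pass were glutamate receptors (4 higher, 8 lower, of 23), GABA receptors (1 and 4 of 14), potassium and HCN channels (5 and 3 of 32), presynaptic release (6 and 5 of 24), and neuropeptides and trophic factors (2 and 7 of 18). Within them Grin2b was higher by 0.67 ± 0.11, Grik1 lower at −2.34 ± 0.33, Hcn2 higher by 0.67 ± 0.12, and the peptide Adcyap1 higher by 1.47 ± 0.18. The glutamate receptor list passed as lower without input replicate 1 (adjusted p = 0.0169).

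Ribosomal protein transcripts rose, with 30 of 42 higher and 0 lower (34 adjusted over the list alone) and a median log2 fold change of 0.88 (camera adjusted p = 3.61e-12, adjusted p = 0.543 with an estimated correlation). Rplp2 rose by 1.48 ± 0.26 and Rpl38 by 1.70 ± 0.32, though these genes have processed copies that can share their reads. Nuclear oxidative phosphorylation genes had 30 of 38 higher and 0 lower (33 adjusted over the list alone), with a median of 0.84 (camera adjusted p = 5.08e-13, adjusted p = 0.385 with an estimated correlation). Ndufa4 rose from 190 ± 60.6 to 580 ± 92.3 CPM, and 3 of the named genes outside the list, Atp5k, Ndufb1-ps and Atp5md, rose by 2.02 ± 0.29, 1.99 ± 0.28 and 1.79 ± 0.26. Mitochondrially encoded transcripts fell (6 of 7 lower, 6 adjusted over the list alone; median −1.44, camera adjusted p = 0.000117, adjusted p = 0.543 with an estimated correlation), with mt-Cytb at −2.07 ± 0.24. Across 16863 genes the log2 fold change correlated with transcript length at a Spearman's rho of −0.29, a correlation across genes, which are not independent replicates. The median was 0.54 in the shortest decile of transcripts, −0.28 in the eighth and −0.02 in the longest.

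Other named genes that rose were Akap9, a kinase anchor of the centrosome and Golgi (chromosome 5, 3928054 to 4081310), from 112 ± 6.48 to 513 ± 29.8 CPM, Ankrd26 (2.13 ± 0.13), the spliceosome component Snrnp70 (1.92 ± 0.11), the noncoding Snhg20 (2.26 ± 0.32), L3mbtl4 (1.81 ± 0.31) and Pet100 (1.76 ± 0.24). Immediate early genes (5 higher, 4 lower, of 24), glucocorticoid response genes (3 and 3 of 15), protein folding genes (4 and 5 of 23), nerve injury genes (3 and 5 of 22), inflammation genes (0 and 2 of 15), translation factors (6 and 1 of 24) and noncoding RNAs (3 and 1 of 11) did not pass as lists. The inflammation list passed as lower without input replicate 2 (adjusted p = 0.0447). Among their members Gap43, a growth cone protein, rose from 566 ± 63.7 to 1481 ± 30.2 CPM, and Egr1 fell by 0.70 ± 0.12 on the log2 scale. The edgeR adjusted p of the genes given as higher or lower in the IP comparison lay below 0.05, with no overlap between the fractions for those taken by fold change.

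The second comparison asked which ribosome-bound transcripts of these neurons differed between cuff and sham mice. No gene passed: of 15957 genes tested, 0 were higher and 0 lower in cuff by edgeR (lowest adjusted p = 0.74), with 1042 at an unadjusted p below 0.05 against 798 for 5% of the tests. That count does not set the real grouping apart. Of 100 splits of the 16 libraries, the real one included, 21 gave as many, and the other splits gave a median of 426. DESeq2 called 4 genes higher and 2 lower. The 4 were Pigt, Slc35f4, Aup1 and Gm12462, and the 2 were Papss2 and Pglyrp1, named because DESeq2 called them. Pigt, a subunit of the enzyme that attaches GPI anchors, was 21.8 ± 2.34 CPM in cuff and 16.01 ± 1.59 in sham (SD, n = 8 each; log2 fold change 0.45 ± 0.10, SE, DESeq2 adjusted p = 0.0241, edgeR adjusted p = 0.74). Slc35f4 was 25.4 ± 3.57 against 17.3 ± 3.10 CPM (0.55 ± 0.12, DESeq2 adjusted p = 0.0353), and Aup1, a protein of lipid droplets and protein quality control, 52.6 ± 5.15 against 40.8 ± 3.42 CPM (0.36 ± 0.09, DESeq2 adjusted p = 0.0369). Papss2, which makes the sulfate donor PAPS, was 3.45 ± 1.40 against 7.79 ± 2.92 CPM (−1.18 ± 0.26, DESeq2 adjusted p = 0.0353). For Pigt, Slc35f4 and Aup1 8 of 8 cuff libraries lay above the sham median, and for Papss2 8 of 8 lay below it. Since DESeq2 called these genes on the same libraries, this separation is no further support. Pglyrp1 (DESeq2 log2 fold change −1.85 ± 0.41) and Gm12462 had 529 and 83 reads in the 16 libraries together, and Gm12462 had none in any sham library. Slc35f4 lies on mm10 chromosome 14 (49298519 to 49526046), Pigt on chromosome 2 (164497520 to 164508301), Aup1 on chromosome 6 (83054521 to 83057808) and Papss2 on chromosome 19 (32595790 to 32667187).

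**Figure D2:**
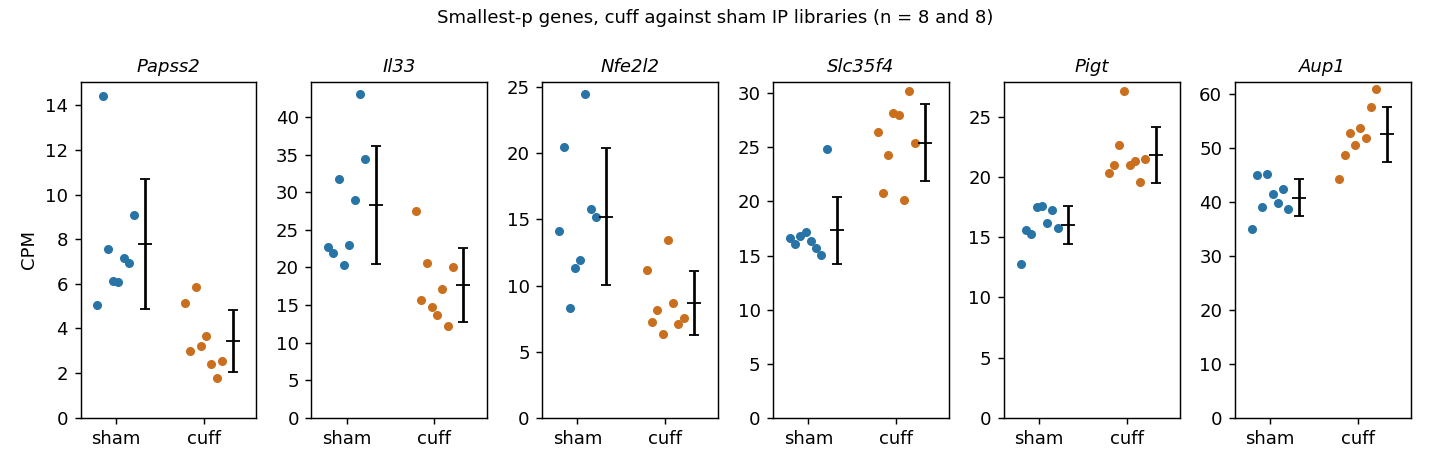
CPM of 6 of the smallest-p genes in the 8 sham and 8 cuff IP libraries (points; bars are mean ± SD, y axes start at 0). Papss2 averages 7.79 in sham and 3.45 in cuff, and none of the 6 genes passed edgeR's adjusted threshold.

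The other genes with the smallest p in cuff, none of which passed edgeR's adjusted threshold, had positive log2 fold changes for Alg1 (0.51 ± 0.13), an enzyme of N-glycan synthesis, the lysosomal protease Ctsl (0.43 ± 0.11), Tmem38a (0.35 ± 0.09), Ifit1bl1 (0.64 ± 0.17), the glucose-6-phosphate transporter Slc37a4 (0.60 ± 0.16), Emc10 (0.35 ± 0.10) and BC004004 (0.34 ± 0.09). They were negative for Prkx (−0.61 ± 0.15), the DNA damage kinase Atm (−0.70 ± 0.18), the antioxidant regulator Nfe2l2 (−0.81 ± 0.21), the alarmin Il33 (−0.68 ± 0.18), Dmd (−0.39 ± 0.11), Cpne3 (−0.85 ± 0.23), Naprt (−0.86 ± 0.24), Rtl5 (−0.86 ± 0.24) and Fam199x (−0.50 ± 0.14). Among the 2511 genes called higher in IP than input and tested here, 0 passed by edgeR when adjusted over them alone (lowest adjusted p = 0.492; 127 at an unadjusted p below 0.05, against 126 for 5%). DESeq2 called 2 of them, Slc35f4 and Aup1, and edgeR called 1, Slc35f4, without sham replicate 8 (adjusted p = 0.0272).

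Gene lists lower in cuff than sham were glucocorticoid response, vascular, oligodendrocyte, oligodendrocyte precursor, inhibitory neuron, astrocyte, inflammation and interferon, and mitochondrially encoded genes, along with the 500 genes of smallest p among those lower in IP than input. These 9 of 37 lists passed camera with the preset correlation, and 0 lists were higher. Of 100 splits of the 16 libraries, the real one included, 68 called as many lists. The other splits called a median of 11, so chance cannot be excluded for these calls. With an estimated correlation 0 of the 37 passed after adjustment. No member of any list passed over all genes tested.

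The glucocorticoid response list, genes that stress hormone induces, had 12 of 15 members with a negative log2 fold change and a median of −0.26 (camera adjusted p = 0.00571, unadjusted p = 0.0047 and adjusted p = 0.174 with an estimated correlation). Its list mean was lower in cuff by −0.18 ± 0.05 (SE, exact permutation p = 0.00295, adjusted over 37 lists p = 0.109). Adjusted over the list alone, 3 members were lower: Mertk at −0.69 ± 0.21, Pdk4 at −1.07 ± 0.36 and Nfkbia at −0.39 ± 0.13. Mertk and Pdk4 were also lower in IP than input, at −1.99 ± 0.28 and −2.35 ± 0.32.

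Vascular markers had 20 of 20 negative estimates and a median of −0.96 (camera adjusted p = 4.68e-08, adjusted p = 0.602 with an estimated correlation), and their list mean differed by −0.55 ± 0.24 (exact permutation p = 0.0409, adjusted p = 0.545). Flt1, an endothelial receptor, was 3.82 ± 1.57 CPM in cuff and 9.19 ± 7.23 in sham. Oligodendrocyte markers had 16 of 17 negative estimates and a median of −0.49 (camera adjusted p = 4.68e-08, adjusted p = 0.602 with an estimated correlation), with Mobp at −0.56 ± 0.22. Oligodendrocyte precursor markers had 10 of 10 negative (median −0.39, camera adjusted p = 0.000523, adjusted p = 0.602 with an estimated correlation) and inhibitory neuron markers 15 of 17 (median −0.37, camera adjusted p = 0.000444, adjusted p = 0.609 with an estimated correlation), with Gad2 at −0.48 ± 0.19. Astrocyte markers had 15 of 16 negative (median −0.24, camera adjusted p = 0.00294, adjusted p = 0.757 with an estimated correlation), of which Aldoc passed adjusted over the list alone. Inflammation and interferon genes had 13 of 15 negative (median −0.33, camera adjusted p = 0.0066, adjusted p = 0.609 with an estimated correlation), of which Il33 passed adjusted over the list alone. Mitochondrially encoded genes had 7 of 7 negative (median −0.97, camera adjusted p = 0.0076, adjusted p = 0.814 with an estimated correlation), and the 500 genes lower in IP a median of −0.11 (camera adjusted p = 1.15e-05, adjusted p = 0.814 with an estimated correlation).

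The non-neuronal index was 3.39 ± 0.32 in cuff and 3.73 ± 0.31 in sham (SD, n = 8 each), a difference of −0.34 (exact permutation p = 0.0486, two-sided), against 4.39 ± 0.13 in input and 3.58 ± 0.08 in IP of naive mice (SD, n = 3 each), libraries of another table and not tested against these. The estimates for its parts were unequal: the vascular list mean was lower in cuff by −0.55, the oligodendrocyte by −0.40, the astrocyte by −0.20 and the microglia by −0.16. Between naive IP and input the vascular list mean differed by only −0.11 ± 0.28 (SE). Whether the index difference measures purification alone stays open. The vascular list fell beyond 5 lists of other cell types by −0.274 (exact permutation p = 0.174). Oligodendrocyte markers fell beyond astrocyte markers by −0.203 (exact permutation p = 0.285). Among the IP libraries the index was highest in sham replicates 7 (4.27) and 6 (4.02). The index difference was no longer past 0.05 without any 1 of sham 2, 5, 6 and 7 or cuff 2, 3, 4, 6 and 7 (exact permutation p from 0.0513 without cuff 6 to 0.0987 without sham 7). Without both sham 6 and 7, chosen after seeing the data, the difference was −0.20 (exact permutation p = 0.198) and 4 lists passed. Monoamine and neuromodulator receptors passed as higher in cuff (adjusted p = 0.0239, against 0.205 with all libraries). Vascular (adjusted p = 0.000208), oligodendrocyte (0.00282) and glucocorticoid response genes (0.0229) passed as with all libraries, and the inhibitory (0.053), precursor (0.053), astrocyte (0.191), inflammation (0.189) and mitochondrial (0.217) lists and the 500 genes (0.0602) did not. Without sham 6 and 7 and cuff 6, also chosen after seeing the data, 9 lists passed, 4 of them among the 9 called with all libraries: vascular (0.000186), oligodendrocyte (0.000186), precursor (0.0255) and glucocorticoid response (0.0255). The others were not called with all libraries: ribosomal proteins (0.0232), choroid plexus (0.0334), noncoding RNAs (0.0342), monoamine receptors (0.0417) and the 500 genes higher in IP (0.0334). With the index in the design, the glucocorticoid list passed (0.0351), and the precursor (0.801) and mitochondrial (0.959) lists did not. The vascular, oligodendrocyte, astrocyte and microglia lists cannot be judged that way, since the index holds their members. Lists that passed with the index and not without it were ribosomal proteins (0.000175), layer 5 extratelencephalic markers (0.0468) and the 500 genes higher in IP (6.56e-05) as lower, and monoamine receptors (0.00115), neuropeptides (0.0235), meningeal (0.0133) and striatal markers (0.0415) as higher. Leaving out a single library ended the astrocyte call (adjusted p = 0.111 without sham 7 and 0.07 without cuff 7) and the mitochondrial call (0.126 without sham 6 and 0.0968 without cuff 7). It also ended the inflammation call (0.0515 without cuff 7) and that of the 500 genes (0.126 without sham 7).

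**Figure D3:**
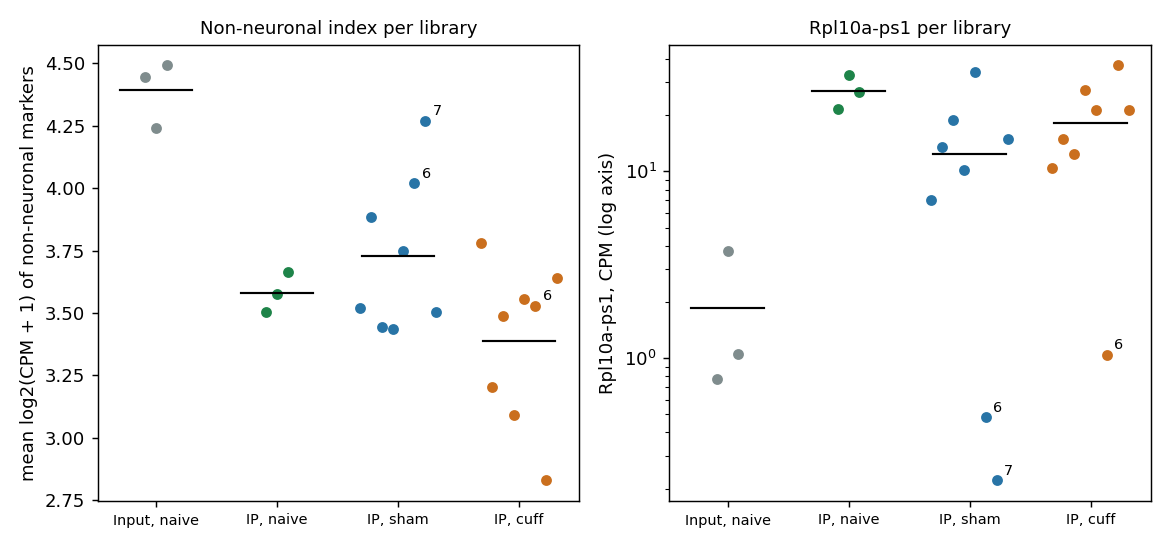
Non-neuronal index (left, mean log2(CPM + 1)) and Rpl10a-ps1 level (right, CPM on a log axis) of each library, with the group mean as a bar (n = 3, 3, 8 and 8). Sham replicates 6 and 7 have the highest indices among the IP libraries, at 4.02 and 4.27, and together with cuff replicate 6 the fewest Rpl10a-ps1 reads, and naive libraries come from a separate table.

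The other lists did not pass in cuff against sham with all libraries (camera adjusted p from 0.0871 for ribosomal proteins to 0.963). Leaving out 1 library let some of them pass. Ribosomal proteins passed as lower without sham 5 (adjusted p = 1.06e-05), sham 7 (0.00162), cuff 2 (0.00226), cuff 6 (0.0145) or cuff 8 (0.0123). Oxidative phosphorylation genes passed as higher without sham 3 (0.0293), sham 4 (0.0163), sham 6 (0.00016), cuff 1 (0.013), cuff 3 (0.0195) or cuff 5 (0.0287). Microglia markers passed as lower without sham 1 (0.0294), sham 8 (0.00455), cuff 1 (0.0161) or cuff 8 (0.0155), and blood markers without sham 5 (0.0216), sham 8 (0.00282) or cuff 6 (0.0406). Postsynaptic scaffolds passed as lower without sham 1 (0.0351), sham 3 (0.0223) or cuff 6 (0.0193), and potassium and HCN channels without sham 1 (0.00649) or sham 8 (0.0132). Noncoding RNAs passed as lower without sham 1 (0.0414) or cuff 6 (0.00637), habenula markers as lower without sham 1 (0.0294), and monoamine receptors as higher without sham 7 (0.0477). The 500 genes higher in IP passed as lower without sham 7 (0.0267).

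For markers of the tagged population, layer 5 extratelencephalic list means differed by 0.09 ± 0.15 (SE, exact permutation p = 0.595), though that list passed as lower with the index in the design (camera adjusted p = 0.0468, against 0.513 as higher without it). Glutamatergic list means differed by −0.02 ± 0.07 (exact permutation p = 0.828), with Slc17a7 at 1063 ± 172 CPM in cuff and 799 ± 186 in sham (log2 fold change 0.41 ± 0.14, not passing). Immediate early genes had 15 of 24 positive estimates (camera adjusted p = 0.963), with Npas4, an activity-induced transcription factor, at 1.26 ± 0.51. List means of glutamate receptors differed by 0.02 ± 0.07, of GABA receptors by 0.02 ± 0.08, of presynaptic release genes by 0.00 ± 0.07 and of postsynaptic scaffolds by −0.09 ± 0.06. Choroid plexus genes followed 2 libraries: Ttr, a choroid plexus transport protein, was 1174 CPM in sham replicate 6 and 412 CPM in cuff replicate 2, with group medians of 4.47 and 7.72 CPM. Without these 2 libraries, or without sham 6 and 7, edgeR again called 0 genes in either direction, with 843 and 903 at an unadjusted p below 0.05. Among lists that did not pass, camera's direction differed in sign from the median or the mean for the choroid plexus list (median −0.75, mean −0.85, camera up), the 500 genes higher in IP, and the layer 6 and 6b, striatal, glutamate receptor, GABA receptor, sodium and calcium channel, presynaptic, protein folding and nerve injury lists.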

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

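The tests of Rpl10a-ps1 and of the lists low in cuff were chosen after the results were seen. The values of 62 genes and lists were searched in the sham and in the cuff group, 124 searches in all, for a library set apart from its group of 8 by a gap above Dixon's critical share of the group's range. This found 14 values, and 5 of them lay in sham replicate 6. The 6.2 expected by chance would hold for independent, normally distributed values. These values are not independent, since Ttr is a member of the choroid plexus list, so no excess is read from the count.

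Sham replicate 6 had 1174 CPM of Ttr (0.0948 to 33.3 in the other sham libraries) and a choroid plexus list mean of 5.383 (others 1.47 to 3.30), and cuff replicate 2 had 411.8 CPM of Ttr (others 1.58 to 10.7). Sham replicate 6 was lowest for Emc10 (149.2 CPM, others 197 to 215) and highest for Atm (27.21 CPM, others up to 18.8) and Naprt (8.693 CPM, others up to 5.11). Sham replicate 7 had the lowest layer 5 extratelencephalic list mean (5.13, others 5.77 to 6.08) and the highest astrocyte list mean (5.989, others up to 5.49). Sham replicate 8 was highest for Slc35f4 (24.83 CPM, others up to 17.2) and lowest for the glucocorticoid response list (4.845, others from 5.02). Sham replicate 2 was highest for Papss2 (14.4 CPM, others up to 9.06). Cuff replicate 4 was highest for Pigt (27.17 CPM, others up to 22.7), cuff replicate 2 for Prkx (13.74 CPM, others up to 9.36), and cuff replicate 7 was lowest for the mitochondrially encoded list (3.975, others from 5.47).

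Rpl10a-ps1 rose most in IP of the named genes, and 605 of its 605 50-base windows (100%) occur in Rpl10a, whose protein carries the tag. Its rise exceeded the median of the ribosomal protein list by 2.956, which argues against that general rise as the cause. A candidate explanation is that reads of the tag's own coding sequence, or of Rpl10a, were placed on this copy, which the shared sequence allows but does not show. No reads were available to tell these sources apart, and no biological explanation was tested.

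Rpl10a-ps1 had 7, 12 and 35 reads in sham 7, sham 6 and cuff 6, against a median of 459.5 (3 of 16 libraries). Depth argued against: the highest of these counts was 7.68% of what depth would give, a test that replaced an undecided earlier one (with total count, Spearman's rho 0.332, permutation p = 0.211, adjusted p = 0.288, and r 0.499, permutation p = 0.0482, adjusted p = 0.0855, or 0.095 without the 2 farthest). Less tagged RNA in these purifications may be a reason, with its own cause untested: the copy's level went with the layer 5 extratelencephalic list mean over 16 libraries (rho 0.571, permutation p = 0.0241, adjusted over 12 p = 0.183, and r 0.67, p = 0.00556, adjusted p = 0.0422). Without the 2 farthest libraries r was 0.546 (permutation p = 0.0366), and within sham it fell from 0.675 to 0.015 and within cuff from 0.649 to 0.311, so r within the groups rests on those libraries, while rho was 0.738 within cuff (permutation p = 0.0458, adjusted p = 0.183) and 0.333 within sham (permutation p = 0.428, adjusted p = 0.467). Not every value goes that way: sham 6 had a layer 5 extratelencephalic mean of 5.85 (rank 7 from the lowest, median 5.98), cuff 6 an index of 3.53 (median 3.53), and the index gave rho −0.471 (permutation p = 0.0672, adjusted p = 0.202) and r −0.645 (permutation p = 0.00703, adjusted p = 0.0422), or −0.286 without the 2 farthest and 0.364 within sham without them.

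Vascular, oligodendrocyte, precursor, inhibitory and astrocyte lists were called low in cuff with the preset correlation and none of them with an estimated one, and microglia, blood, meningeal, striatal and choroid plexus lists were not called. Whether sham 6 and 7 were the cause stays open: 3 of the 9 lists were also called without both, but other splits of the libraries called a median of 11 lists, so calls left over decide nothing. A smaller share of RNA of all other cell types in cuff purifications cannot be told apart from a change in single types, since the vascular list fell beyond the other 5 lists by −0.274 (exact permutation p = 0.174) and oligodendrocyte beyond astrocyte markers by −0.203 (exact permutation p = 0.285). The 500 genes lower in IP, which such a share would lower, differed by −0.104 (exact permutation p = 0.337), and the spread between the 16 libraries keeps this open. An effect of the cuff on these cells stays open too, untested.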

How the results depend on the processing

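Leaving out libraries in sets, and each library in turn for the lists, was chosen after the data were seen. For IP against input, 1515 values of named genes under an alternative kept their direction and side of the threshold, 55 lost the call, 25 gained it and 0 reversed. A fold of at least 1.5 left 1666 genes higher, as fewer genes can pass. Leaving out 1 library gave 1093 (without input 3) to 2730 (without input 1) genes higher and 1265 to 2870 lower. Fewer libraries were then fitted, and why input 3 moved them most was not tested. An estimated correlation left 0 lists called in IP against input and 0 in cuff against sham. How much of this comes from the members' own correlation was not tested.

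For cuff against sham, DESeq2 called 4 genes higher and 2 lower, and 2 among genes higher in IP. Within these, leaving out 1 library gave 0 to 1 (without sham 8). The cause was not tested. The other edgeR and limma settings called 0 genes. With 1 library left out, the lists called ranged from 6 (without cuff 7) to 14 (without sham 1). They were 4 without sham 6 and 7, and 9 without sham 6, 7 and cuff 6, of which 4 were among the 9 called with all libraries. The index difference with 1 library left out ranged from −0.395 (without cuff 1) to −0.259 (without cuff 7). It was −0.419 with a pseudocount of 0.1, −0.2 without sham 6 and 7 and −0.22 without sham 6, 7 and cuff 6. The cause was not tested.

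Among the lists called with or without the index in the design, 7 changed direction with it. Their camera adjusted p with the index was 0.0468 (layer 5 extratelencephalic), 0.819 (inhibitory), 0.303 (astrocyte), 0.0235 (neuropeptide), 0.819 (inflammation), 0.161 (500 genes lower in IP) and 6.56e-05 (500 genes higher in IP). The index holds the astrocyte markers, so that list cannot be judged this way. For the other lists the cause was not tested. Ribosomal protein (0.000175), monoamine receptor (0.00115), meningeal (0.0133) and striatal lists (0.0415) passed with the index. The 500 genes higher in IP also reversed without sham 7 (0.0267, highest 0.944 without cuff 8) and without sham 6, 7 and cuff 6 (0.0334).

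With the replicate number as a block, layer 6 and 6b markers passed in IP against input (adjusted p = 0.032), and Chrna3 did not (adjusted p = 0.0548). In cuff against sham, where the numbers do not pair libraries, blood (0.0472), ribosomal protein (0.0139) and noncoding lists (0.0193) passed with the block. Simulated data had these depths and each gene's own spread, with genes drawn independently. There, 41.8% of 1.5-fold changes were recovered for cuff against sham and 23.9% for IP against input. Recovery may differ where genes vary together.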

Other observations

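The tests against the glutamatergic list were chosen after the result was seen, and those on transcript length and on other splits before. Ribosomal protein and nuclear oxidative phosphorylation transcripts were high in IP. Short transcripts were too. Both list medians (0.88 and 0.84) lay at percentile 100 of 10000 random lists matched on length and expression (random medians 0.50 and 0.49). The length used was that of each gene's longest annotated transcript, which need not be the one expressed. The random lists also held unrelated genes, whereas members of these lists may vary together. Length as the whole cause thus stays open. Removal of other cells' RNA would raise glutamatergic markers alike, and the list means exceeded theirs by 0.712 ± 0.205 and 0.732 ± 0.181 (SE, n = 3 each). Those markers went both ways, however (4 higher, 5 lower, of 15). The layer 5 extratelencephalic list mean rose by 0.939 ± 0.114 (SE), against 0.771 and 0.79 for these 2 lists. The test therefore cannot decide whether such removal is the cause. Reads shared with processed copies stay open for the ribosomal proteins. A hypothesis that stays open is that these transcripts were more ribosome-bound, or more abundant in the tagged neurons, which these libraries cannot separate.

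In the 10 splits of the 6 naive libraries 1, the real one, gave 4939 genes and the highest other 0, and 2 gave at least the real 15 lists (highest other 16, or 14 among splits that part all 3 pairs). These splits are too few for a share under 0.05. Of 100 splits of the 16 sham and cuff libraries, 100 gave as many genes as the real 0 (highest other 973), and 100 as many among genes higher in IP (highest other 943). With 0 real calls these results were fixed in advance and decide nothing. As many lists as the real 9 were called in 68 splits (highest other 30), so chance cannot be excluded for the lists. Of the 99 other splits, 2 gave any gene. The split with 973 genes points to a structure of the samples, and what it is was not tested.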
